A study of Homo sapiens with 6 samples.

How the data were processed

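RNA of 6 samples of the RL cell line was analysed, 3 grown as multicellular aggregates (MALC, 10 days) and 3 from suspension culture in exponential growth. Per the labels' protocols, total RNA was extracted with Trizol, and 200 ng were amplified and labelled with biotin by the one-cycle procedure for Affymetrix U133 Plus arrays. The values deposited by the authors were linear intensities, 1 per probe set and array, for 54675 probe sets. MAS5 is the only tool named in the submitters' processing notes. Its version and role, the background correction and the normalization were not given in the sources used here. The quartiles of the 6 columns lay close together (25th percentiles 27.1 to 27.7 in MALC and 27.8 to 28.3 in suspension, 75th percentiles 320 to 329 and 303 to 311), and the lowest value was 7.8. If the arrays had been scaled to each other before deposit, a shift of all transcripts between the groups would not be seen. No detection calls were used here, and scanner files were not analysed here.

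Groups and sample numbers were taken from the sample titles. Of 54613 probe sets that are not controls, 41091 named 1 gene symbol, 1801 several and 11721 none in the platform annotation; symbols were updated through Entrez identifiers with a RefSeq gene table (assembly GRCh38.p14), which held 41037 of the 1-gene probe sets, and 54 kept the annotation's symbol. No genome was used, so no positions are given. Genes were named from probe sets with 1 symbol only, and probe sets of HLA and immunoglobulin genes can share signal. The 62 control probe sets were kept out of the tests.

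The intensities were set to log2(value + 16). Probe sets with a mean log2 value at or above the 40th percentile were kept (32768 probe sets; a signal of 53.4), and each gene was represented by its probe set with the highest mean, giving 13765 genes. No further normalization was applied. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, two-sided, group as the only term), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Adjusted p-values of genes in the text come from this model, means ± SD from the linear intensities. The 26 gene lists and 6 lists of markers of other cell types were written before the data were examined, as were the tests, the rule for named genes and 16 alternatives. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, two-sided and adjusted over the lists; camera with an estimated correlation and fry were alternatives. Counts of list members are given over all genes tested and adjusted over the list alone.

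Genes were named by a fixed rule, which gave 94 genes: the 10 largest rises and the 10 largest falls among genes past the threshold whose groups did not overlap; up to 3 members of each list with the largest change past the threshold; and MS4A1, BCL2, BCL6, MKI67, MYC, CDKN1A, CDKN1B and VEGFA. Other members, and transcripts that differed between arrays of 1 group, were named after their values were seen.

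The sample numbers are shared by the groups. The labels do not say what a number marks. Deviations from the group means correlated at 0.28, 0.18 and 0.19 for the samples numbered 1, 2 and 3. MALC 2 with suspension 3 and MALC 3 with suspension 2 correlated at 0.15 and 0.2. The numbers 2 and 3 were thus not told apart, and both differed from number 1. These values do not establish a pairing of single samples. The main fit did not use the number, which entered as a block in an alternative only. The fit with the number as a block is given where it changed the call of a list or of a gene named in the text, and for the larger shifts in the counts of list members. No array columns were identical, and Pearson correlations across probe sets lay between 0.9949 and 0.9985 within groups and between 0.9769 and 0.9888 between groups. Samples 2 and 3 correlated at 0.9984 in MALC and 0.9985 in suspension, and sample 1 with either at 0.9949 to 0.9956. The 3 samples of a group may thus stand for fewer independent units than their number. A fit without sample 1 of a group leaves the nearly alike samples 2 and 3 there. Its p-values then rest on a small spread in that group and can be small without larger effects. Array weights can act alike if they favour samples 2 and 3, and the weights were not examined here. The median SD within a group was 0.087 (MALC) and 0.079 (suspension) on the log2 scale. The 3′ to 5′ signal ratio of the ACTB controls was 1.22 to 1.33 in MALC and 1.31 to 1.54 in suspension, and that of GAPDH 1.01 to 1.02 in MALC and 1.04 to 1.06 in suspension.

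The gene test was tested on simulated data with the means and spread of these arrays, drawn independently for each gene. There 67, 67 and 66 genes were changed by 0.5, 1 and 2, whereas 42.7% of the genes tested changed in the real comparison. Of genes changed by 0.5, 1 and 2 on the log2 scale in the simulated MALC against suspension comparison, 68.7%, 97% and 100% were recovered, with 11 false calls among 13765 genes. In the simulation of gene lists 1 of the lists that had not been shifted was also called. Correlated genes and effects shared by all genes of an array were not simulated, so these error rates do not cover them.

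The alternatives changed the pseudocount (1 or 64), the filter (none, or the 60th percentile), the normalization (quantile, or median centring), the probe sets (their mean, or none with the suffix _s_at or _x_at), the variance prior, array weights, the block, each array left out in turn, probe sets in place of genes, and the list test. Chosen after seeing the data were 4 more: no pseudocount, both arrays numbered 1 left out, suspension 2 and suspension 3 left out together, and the block with an estimated correlation. With 3 against 3 samples the smallest two-sided p of an exact permutation test is 0.1, so such a test of a single value cannot pass 0.05. Figures were drawn with matplotlib 3.10.9.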

Results

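Gene expression was measured in RL cells, an established human B lymphoid cell line carrying the translocation typical of follicular lymphoma. Untreated cells were grown in suspension and collected during exponential growth, or as MALC, the name for multicellular aggregates of these cells, and collected after 10 days. Each culture form was represented by 3 samples, numbered 1 to 3, and each sample by a single Affymetrix U133 Plus array with 54675 probe sets. The deposited values were linear signals with medians between 80.7 and 81.7 in all 6 arrays, and the number of arrays limits the precision. Other percentiles separated the groups: the 75th was 320 to 329 in MALC and 303 to 311 in suspension, and the 95th 2352 to 2418 and 2494 to 2500. The samples were not said to come from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The 2 groups differed in culture form and may also have differed in culture age and growth phase, which then cannot be separated from it. No age was given for the suspension cultures, and exponential growth was stated for them alone.

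The comparison asked how expression in aggregates differed from that in suspension. In MALC, 22 of 28 measured hypoxia response genes rose, with a median fold of 2.53, among them SLC2A3, which encodes a glucose transporter, and VEGFA, an angiogenic growth factor. All 40 measured genes of the G1/S and DNA replication list fell (median log2 change −0.68), and 26 of 27 ribosome biogenesis and MYC target genes fell (median −0.74). CDKN1B, the cyclin-dependent kinase inhibitor p27, rose 3.76-fold, from a signal of 889.8 ± 90.9 in suspension to 3389 ± 386 in MALC (SD, n = 3 each). Of 13765 genes tested, 5877 changed, 2611 of them higher and 3266 lower in MALC, whereas MS4A1, which encodes the B cell antigen CD20, had signals of 12590 ± 1100 in MALC and 13170 ± 2010 in suspension (log2 change −0.06, adjusted p = 0.713).

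**Figure D1:**
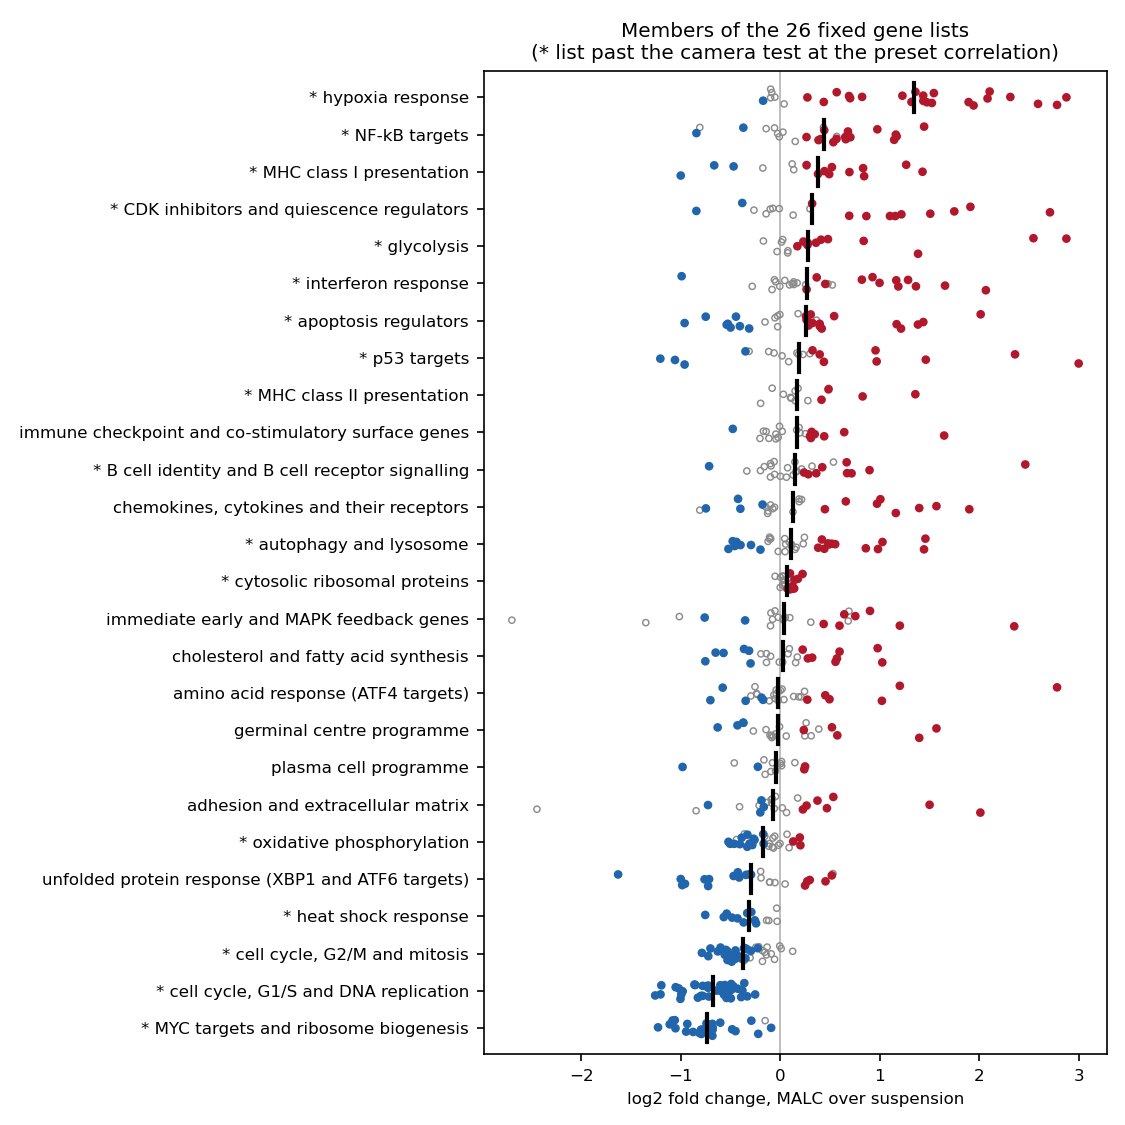
Log2 fold change (MALC over suspension) of every tested member of the 26 gene lists fixed beforehand, 1 point per gene; filled points passed the gene test (red higher, blue lower), open points did not, vertical bars mark list medians, and asterisks mark lists past the camera test at its preset correlation. The hypoxia response list has the highest median (1.34) and the ribosome biogenesis list the lowest (−0.74).

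Changes at least 2-fold in size were mostly rises, with 383 genes higher and 110 lower in MALC. The counts came from limma with Benjamini-Hochberg adjustment at 0.05, and 7087 genes lay under an unadjusted p of 0.05. Of the genes tested, 56.9% had groups that did not overlap, against the 10% that chance gives for 3 against 3. The first principal component held 82.6% of the variance and separated the groups, with MALC 1 at −13.6 lying nearer to the suspension arrays (23.7 to 29.1) than MALC 2 and MALC 3 did (−30 and −32.8). Fold changes are on the log2(signal + 16) scale, which understates those of dim genes. The total was 2855 with suspension 2 and suspension 3 left out, an alternative chosen after seeing the data, and 8880 with array weights; without MALC 2 the genes lower in MALC numbered 2113.

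Within the hypoxia response list, SLC2A3 rose 7.33-fold (1535 ± 202 in MALC against 194.8 ± 13.3 in suspension, n = 3 each, adjusted p = 1.97e-05). DDIT4, an inhibitor of mTORC1 signalling, rose 6.86-fold, NDRG1, a hypoxia-induced gene, 6.01-fold, and VEGFA 3.84-fold (3914 ± 177 against 1008 ± 59.5). STC2 alone of the 28 fell, with a log2 change of −0.17, and 5 members did not pass; adjusted over the list alone the counts were again 22 and 1, and the STC2 call was lost when any array except MALC 1 was left out. The list stood above other genes (camera adjusted p = 1.11e-12; adjusted p = 0.295 with an estimated correlation). Of 18 glycolysis genes, 12 rose and none fell (12 and 1 adjusted over the list alone), with a median log2 change of 0.27. ALDOC, an aldolase, rose 5.82-fold and ENO2, an enolase, 2.61-fold, while TPI1 and PFKL rose by 0.17 and 0.23 on the log2 scale. The glycolysis list had a camera adjusted p of 3.41e-06, and adjusted p = 0.306 with an estimated correlation; without MALC 1, and with the sample number as a block, 1 member fell. Among 30 oxidative phosphorylation genes, 13 fell and 3 rose (15 and 3 adjusted over the list alone), with a median log2 change of −0.17; without MALC 2 these counts were 8 and 0. The complex I genes NDUFA9, NDUFS1 and NDUFS3 had log2 changes of −0.52, −0.50 and −0.46, whereas NDUFA1, UQCRB and COX7C rose by 0.20, 0.20 and 0.13. The list passed with camera adjusted p = 0.0284, not with an estimated correlation (adjusted p = 0.602), and was lost without MALC 3 (adjusted p = 0.0847), without suspension 1 (0.0583), after quantile normalization (0.208), with the mean of probe sets (0.199), without _s_at and _x_at probe sets (0.163) and by fry (0.0515). The NDUFS1 call was lost without any array except MALC 1, with adjusted p up to 0.12, and without _s_at and _x_at probe sets (0.191).

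The G1/S and DNA replication list was the most uniform, since 40 of 40 members fell, also adjusted over the list alone. MCM10 and CDC6, needed to start DNA replication, fell to 0.418 and 0.434 of their suspension level, and CHAF1A, a chromatin assembly factor subunit, to 0.437 (camera adjusted p = 4.98e-11; adjusted p = 0.423 with an estimated correlation). Of 40 G2/M and mitosis genes, 26 fell and none rose (27 and 0 adjusted over the list alone), with a median log2 change of −0.37. The G2/M falls numbered 16 without MALC 2 and 17 without MALC 3, suspension 2 or suspension 3, and 3 without suspension 2 and suspension 3, when those of the G1/S list numbered 22; with the sample number as a block 28 G2/M genes fell and 1 rose. The mitotic kinase gene PLK1 was 1.73-fold lower, FOXM1, a transcription factor of mitotic genes, 1.65-fold, and KIF11, a spindle motor, 1.63-fold (camera adjusted p = 3.86e-05; adjusted p = 0.602 with an estimated correlation). MKI67, the Ki-67 proliferation marker, had 3112 ± 631 in MALC and 3649 ± 200 in suspension and did not pass (adjusted p = 0.167, but 0.00196 without MALC 1, 0.00194 with array weights and 0.0402 with the mean of probe sets). In the fit over probe sets, its other probe sets had log2 changes of −0.59 (adjusted p = 0.00714), −0.34 (0.0148) and −0.25 (0.224).

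Of 19 CDK inhibitor and quiescence genes, 10 rose and 2 fell (11 and 2 adjusted over the list alone). YPEL3, a growth-suppressing gene, rose 6.54-fold (2943 ± 824 against 435.5 ± 119), PNRC1 3.36-fold and CDKN1B 3.76-fold, while the pocket protein gene RBL1 fell with a log2 change of −0.84 and TOB1 with −0.38. The falls of this list numbered 0 in limma without MALC 2 or suspension 2 and 1 without MALC 3, suspension 1 or suspension 3. The list passed (camera adjusted p = 0.00169; adjusted p = 0.306 with an estimated correlation). CDKN1A, the p21 gene, had signals of 841.7 ± 130 and 677 ± 21.8 in MALC and suspension and did not pass (adjusted p = 0.0598, but 0.031 with array weights). Of 21 p53 target genes, 8 rose and 4 fell (9 and 4 adjusted over the list alone). TP53INP1, a stress-induced p53 target, rose 7.98-fold, GADD45B 5.12-fold and GADD45A 2.75-fold, the latter pair encoding stress sensors. In the fit over probe sets a dimmer TP53INP1 probe set did not pass (log2 change 0.15 against 2.996, adjusted p = 0.0856). BAX, a pro-apoptotic effector, TIGAR, AEN and TP53I3 fell, with log2 changes of −0.96, −1.06, −1.21 and −0.35. The p53 list passed (camera adjusted p = 0.0231; adjusted p = 0.306 with an estimated correlation), but not without MALC 1 (0.0628), without suspension 1 (0.0704) or with array weights (0.0587). The GADD45B call was lost without _s_at and _x_at probe sets (0.115), where a dimmer probe set with a log2 change of 0.19 stood for the gene. The main log2 change was 2.36, and the remaining GADD45B probe sets gave 1.61 and 1.96.

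**Figure D2:**
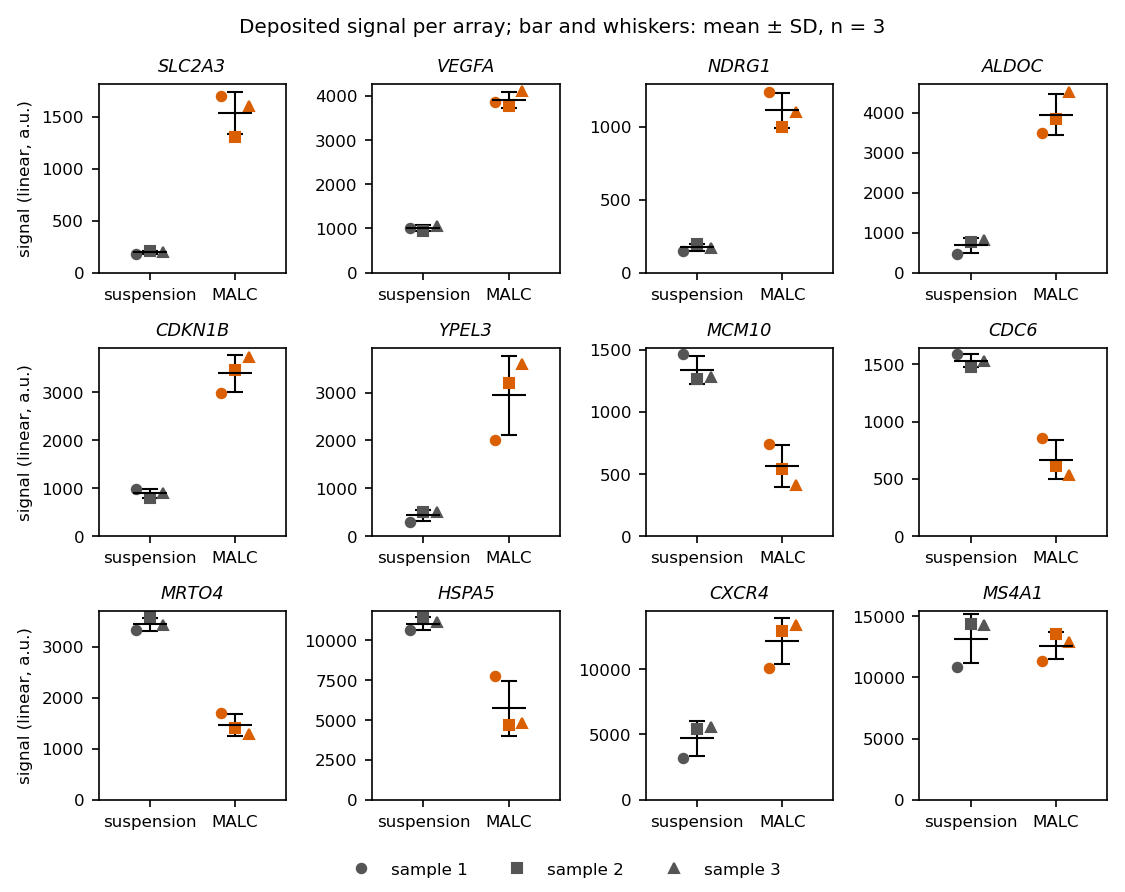
Deposited linear signal (arbitrary units) of 12 named genes in each of the 6 arrays; symbols give the sample number, horizontal bars the mean and whiskers the SD (n = 3). The 3 MALC values of SLC2A3 (1309 to 1697) lie above all suspension values (181.9 to 208.5), those of MCM10 (409.4 to 743.5) below all suspension values (1268 to 1465), and those of MS4A1 overlap.

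Ribosome biogenesis and MYC target genes fell almost throughout, 26 of 27 also adjusted over the list alone. MRTO4, NOP16 and NOP2, which act in assembly of the large ribosomal subunit, were 2.34-, 2.16- and 2.12-fold lower (camera adjusted p = 4.29e-11; adjusted p = 0.334 with an estimated correlation). MYC itself was the member that did not pass, at 6080 ± 297 in MALC and 6786 ± 822 in suspension (adjusted p = 0.191). Cytosolic ribosomal protein genes moved little, 10 of 24 rising and none falling, also adjusted over the list alone, with a median log2 change of 0.07. The rises numbered 3 without MALC 2 or MALC 3, 5 without suspension 2 and 4 without suspension 3. RPL18, RPS25 and RPL11 rose 1.17-, 1.13- and 1.10-fold (camera adjusted p = 0.000252; adjusted p = 0.443 with an estimated correlation, and 0.0863 without _s_at and _x_at probe sets). The RPS25 call was lost without MALC 2, MALC 3, suspension 1 or suspension 2 (adjusted p up to 0.108), after median centring (0.0598) and without trend (0.0756), that of RPL11 without trend (0.0659), and that of RPL18 with the mean of probe sets (0.263).

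Of 14 heat shock genes, 10 fell and none rose, also adjusted over the list alone, with STIP1, FKBP4 and HSPH1, cochaperones of HSP90 or HSP70, 1.69-, 1.48- and 1.45-fold lower (camera adjusted p = 0.000252; adjusted p = 0.306 with an estimated correlation). Of 25 unfolded protein response genes, 13 fell and 5 rose (14 and 6 adjusted over the list alone). SDF2L1 was 3.09-fold lower, PDIA3, a disulfide isomerase, 2-fold lower, and HSPA5, the main endoplasmic reticulum chaperone, 1.98-fold lower (5731 ± 1740 against 11050 ± 398). The rises numbered 3 without any single MALC array or suspension 3. This list did not pass (camera adjusted p = 0.0557), but passed with the sample number as a block (0.035), without MALC 1 (0.0155), without suspension 3 (0.0462), with array weights (0.0333), without the filter (0.038), with the stricter filter (0.0413) and by fry (0.0274). Of 29 amino acid response genes, 6 rose and 5 fell, also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.546, its median of −0.02 differing in sign from its mean of 0.13 and from the test). Its rises numbered 3 without suspension 2 or suspension 3, and its falls 11 without MALC 1, 2 without suspension 1 and 3 without any of the other arrays; with the sample number as a block 9 rose and 8 fell. DDIT3, the stress transcription factor CHOP, rose 2.03-fold and ATF3 2.30-fold. The ATF3 rise was largest in MALC 1 (382.3 against 128.7 and 131.3 in MALC 2 and MALC 3, and 61.07 to 84.12 in suspension). Without MALC 1 or MALC 2 another ATF3 probe set became the brightest. Its log2 change was −0.02 without MALC 1 and 0.29 without MALC 2 (adjusted p = 0.156). The ATF3 call was also lost without suspension 1 (adjusted p = 0.0935), suspension 2 (0.0571) or suspension 3 (0.073). It was lost as well with the mean of probe sets (0.0651) and without _s_at and _x_at probe sets (0.416). Of 25 cholesterol and fatty acid synthesis genes, 8 rose and 6 fell, also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.185, but 0.028 without _s_at and _x_at probe sets). STARD4, a sterol transfer protein, and LSS, lanosterol synthase, rose 2.03- and 1.97-fold, whereas FASN, fatty acid synthase, was 1.69-fold lower.

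Several immune gene lists passed as higher in MALC at the preset correlation, and none of them with an estimated correlation. Of 27 interferon response genes 12 rose and BST2 alone fell (log2 change −0.99), also adjusted over the list alone. IFI44L rose 4.18-fold over a suspension signal of 33.78 that was not shown to be above background, the RNA sensor gene IFIH1 3.15-fold and IRF7, an interferon regulatory factor, 2.57-fold (camera adjusted p = 0.000172; adjusted p = 0.423 with an estimated correlation). The interferon median of 0.26 was 0.13 without suspension 1, 0.05 with 5 members lower without both arrays numbered 1, and 0.48 without suspension 2 and suspension 3. The BST2 call was lost without MALC 2, MALC 3, suspension 2 or suspension 3 and with the sample number as a block (adjusted p = 0.0524), and without MALC 1 the interferon falls numbered 2. Of 26 NF-kB targets, 15 rose and 2 fell (17 and 3 adjusted over the list alone). MAP3K8, a kinase upstream of NF-kB and ERK, rose 2.72-fold, BCL2A1, an anti-apoptotic BCL2 relative, 2.25-fold and LTB, lymphotoxin beta, 2.23-fold, while SOD2 and PLEK fell, with 4 falls without suspension 1 (camera adjusted p = 0.000172; adjusted p = 0.306 with an estimated correlation). The log2 change of LTB of 1.16 was 0.76 without suspension 1, and its call was lost without MALC 3 (adjusted p = 0.0578).

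Of 17 MHC class I presentation genes, 10 rose and 3 fell (11 and 3 adjusted over the list alone). NLRC5, the class I transactivator, rose 2.69-fold and ERAP2, a peptide-trimming protease, 2.40-fold, whereas PDIA3, TAP2 and CALR fell (camera adjusted p = 0.00198; adjusted p = 0.423 with an estimated correlation). Of 14 MHC class II genes 4 rose and none fell, also adjusted over the list alone. HLA-DQB1 rose 2.56-fold (10560 ± 1170 against 4207 ± 1100), CIITA, the class II transactivator, 1.77-fold and CTSS 1.40-fold; HLA probe sets can share signal between members. The class II list passed (camera adjusted p = 0.0254; adjusted p = 0.602 with an estimated correlation), but not without MALC 3 (0.0508), without suspension 1 (0.28, its median of 0.16 falling to −0.01), with array weights (0.0587), with the stricter filter (0.0573) or by fry (0.225). Its median was 0.31 to 0.33 without MALC 1, suspension 2 or suspension 3, its rises numbered 2 without MALC 2 or MALC 3, and 1 member fell without MALC 1. With the sample number as a block 7 class II genes rose and 1 fell. The CIITA call was lost without MALC 2 (adjusted p = 0.0709) or MALC 3 (0.0673).

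Of 28 B cell identity and receptor signalling genes, 9 rose and FCRLA fell (log2 change −0.71), also adjusted over the list alone. CD24, a surface glycoprotein, rose 5.50-fold, the tetraspanin gene CD37 1.86-fold and PIK3CD, the leukocyte PI3-kinase, 1.64-fold. The B cell rises numbered 14 with the sample number as a block and 5 without MALC 2, and the falls 2 without MALC 1, MALC 3 or suspension 1. The list passed (camera adjusted p = 0.014; adjusted p = 0.601 with an estimated correlation), but not without suspension 1 (0.0704), without _s_at and _x_at probe sets (0.0985) or by fry (0.0939). The germinal centre list did not pass (camera adjusted p = 0.188), with 5 of 22 members higher and 4 lower, also adjusted over the list alone, and a median of −0.03 that differed in sign from its mean of 0.13 and from the test. Its falls numbered 0 in limma without MALC 3 or suspension 2 and 1 without MALC 2 or suspension 3, and its rises 8 with the sample number as a block. CXCR5 and CXCR4, chemokine receptors of follicle positioning, rose 2.96- and 2.63-fold, and LMO2 was 1.55-fold lower, a call lost without MALC 2 (adjusted p = 0.0687), MALC 3 (0.0505) or suspension 2 (0.0605). BCL6, the germinal centre repressor, had 13530 ± 707 in MALC and 11480 ± 1700 in suspension (adjusted p = 0.0768, but 0.0114 with the sample number as a block, 0.00418 without suspension 1 and 0.00047 with array weights). Its log2 change was 0.25, and 0.36 without suspension 1, where the nearly alike suspension 2 and suspension 3 remain. In the fit over probe sets another BCL6 probe set passed (log2 change 0.36, adjusted p = 0.0314), and the remaining probe set gave 0.13 (adjusted p = 0.592). The plasma cell list did not pass (camera adjusted p = 0.887, but 0.0303 by fry), with 2 of 15 members higher and 2 lower (1 and 1 adjusted over the list alone). The rises numbered 0 without MALC 2 and 1 without MALC 3, suspension 2 or suspension 3, and the falls 4 without MALC 1 and 1 without MALC 2, MALC 3 or suspension 2. FKBP11, a folding enzyme of secretory cells, was 1.97-fold lower, while XBP1 and DERL3 rose 1.19- and 1.18-fold. The XBP1 call was lost without MALC 2 (adjusted p = 0.06), and that of DERL3 without any array except MALC 1 (up to 0.146), without the filter (0.0603), after quantile normalization (0.124) and after median centring (0.0676).

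Of 21 immune checkpoint and co-stimulatory genes 7 rose and NCR3LG1 alone fell (1.39-fold lower), also adjusted over the list alone. TNFRSF14, a receptor lost in many follicular lymphomas, rose 3.13-fold and CD46, a complement regulator, 1.56-fold. The rises numbered 3 without MALC 2 and 4 without MALC 3 or suspension 3, and the falls 2 without MALC 1. This list did not pass (camera adjusted p = 0.0669), but passed with the sample number as a block (0.0273), without suspension 2 (0.0463), without _s_at and _x_at probe sets (0.0275) and by fry (0.0158). Chemokine, cytokine and receptor genes did not pass as a list (camera adjusted p = 0.137), with 8 of 23 higher and 4 lower (8 and 5 adjusted over the list alone), and CCR7, a lymph node homing receptor, rose 3.73-fold. The rises of this list numbered 5 without MALC 3, and the falls 1 without MALC 2 and 2 without suspension 3.

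Apoptosis regulators changed in both directions, 14 of 29 rising and 8 falling (16 and 8 adjusted over the list alone), with 5 falls without MALC 2. The pro-apoptotic BH3-only genes HRK and BCL2L11 rose 4.03- and 2.61-fold and BNIP3, a mitophagy receptor, 2.71-fold, beside the anti-apoptotic BCL2A1, whereas BAX, FADD and BAK1 fell, with log2 changes of −0.96, −0.75 and −0.54. The list passed (camera adjusted p = 0.0231; adjusted p = 0.306 with an estimated correlation), but not without MALC 1 (0.0719), with the stricter filter (0.0668), with the mean of probe sets (0.0661), without _s_at and _x_at probe sets (0.0879) or with array weights (0.065). BCL2 had 342.9 ± 12.4 in MALC and 284.8 ± 26.3 in suspension (log2 change 0.26, adjusted p = 0.0347). This BCL2 call was lost without MALC 2 (0.118), MALC 3 (0.075), suspension 2 (0.12) or suspension 3 (0.0937), after quantile normalization (0.112) and with the mean of probe sets (0.633), and a probe set without such a suffix gave a log2 change of −0.04. Of 34 autophagy and lysosome genes, 12 rose and 7 fell, also adjusted over the list alone; the falls numbered 3 without MALC 2 and 4 without MALC 3 or suspension 2. NPC2, a lysosomal cholesterol transporter, rose 2.75-fold, SQSTM1, an autophagy receptor, 2.72-fold and MAP1LC3B, an autophagosome protein, 2.04-fold, while LAMP1 and CTSZ fell (camera adjusted p = 0.00594; adjusted p = 0.306 with an estimated correlation).

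The adhesion and extracellular matrix list did not pass (camera adjusted p = 0.494, direction up against a median of −0.07), with 7 of 24 members higher and 4 lower, also adjusted over the list alone. The falls numbered 7 without suspension 1, 1 without MALC 3 or suspension 2, and 2 without any of the other arrays. SDC4, a heparan sulfate proteoglycan, rose 4.02-fold and LGALS1, galectin-1, 2.83-fold, and the integrin gene ITGB7 was 1.65-fold lower. Stromal transcripts differed between the suspension arrays. FN1, fibronectin, had a signal of 1988 in suspension 2, 332.4 in suspension 3, 60.07 in suspension 1 and 49.29 to 55.57 in MALC (log2 change −2.44, adjusted p = 0.0825, but 0.0464 with the sample number as a block). COL1A1 had 1130 and 359 in suspension 2 and suspension 3 against 11 in suspension 1, and POSTN had 1110, 21.2 and 19.7 in suspension 2, 3 and 1. For COL1A1 and POSTN the probe set that ranged most between the arrays is given. The fixed fibroblast marker list did not pass (camera adjusted p = 0.287), with 1 of 11 tested members, THY1, lower. Nor did the T and NK cell (0.929), epithelial (0.929) or endothelial (0.929) lists, whereas the monocyte and erythroid lists had under 5 tested members; LCK and PRF1 rose and AIF1, KRT7 and AHSP fell, also adjusted over the list alone except AIF1.

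The immediate early and MAPK feedback list did not pass (camera adjusted p = 0.136), with 7 of 24 higher and 2 lower (6 and 0 adjusted over the list alone); without suspension 2 it passed (0.0454), and without suspension 1 its direction turned (median −0.03), with 6 falls. The falls numbered 0 in limma without MALC 2, MALC 3, suspension 2 or suspension 3. RGS1, a regulator of G protein signalling, rose 5.09-fold and JUND, an AP-1 subunit, 1.87-fold; a dimmer JUND probe set fell (log2 change −0.27, adjusted p = 0.0143), and with the mean of probe sets JUND did not pass (0.0545). EGR1 had signals of 1218 and 1224 in suspension 2 and suspension 3 but 59.53 in suspension 1 and 48.22 to 75.79 in MALC (adjusted p = 0.0596, but 0.0444 with the sample number as a block). RGS1 had 259.5 and 267.9 in suspension 2 and suspension 3 and 42.4 in suspension 1, below the MALC values of 700.8 to 983.4, and CD69, a lymphocyte activation antigen, had 450.5 and 462.5 against 31.99, with 292.5 to 454 in MALC.

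**Figure D3:**
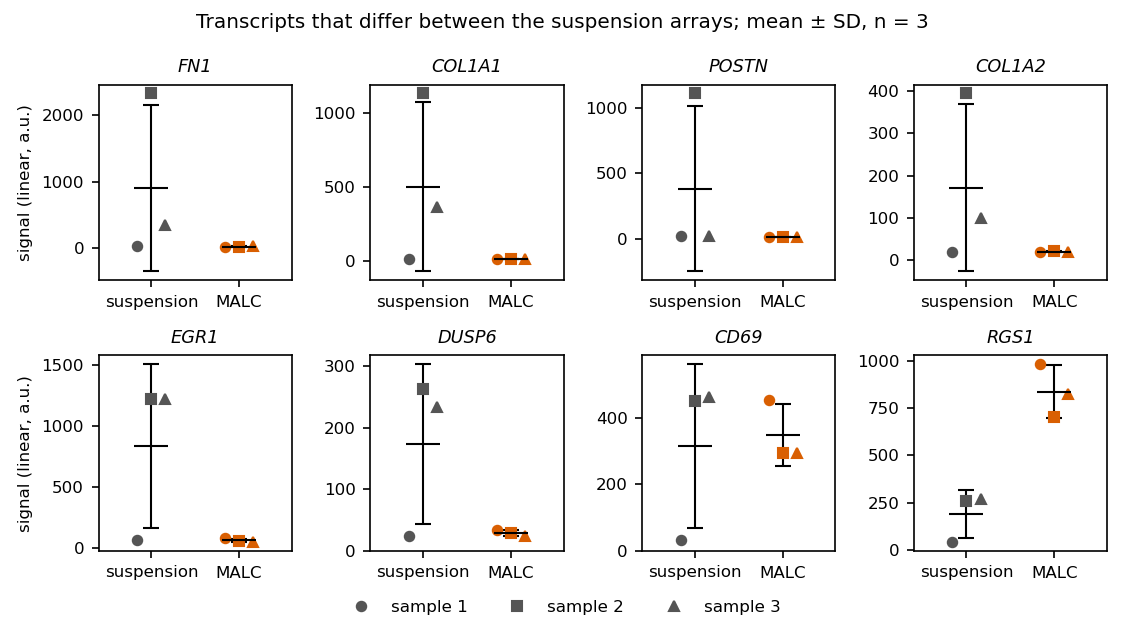
Deposited linear signal (arbitrary units) of 4 stromal transcripts (upper panels, FN1 with its brightest probe set for this pattern) and 4 early response transcripts (lower panels) in each array; symbols give the sample number, horizontal bars the mean and whiskers the SD (n = 3). COL1A1 is seen in suspension 2 (1130) and suspension 3 (359) alone, and EGR1 lies at 1220 in both against 59.5 in suspension 1.

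The 10 largest rises with groups that did not overlap were led by LINC01857, a long non-coding RNA, at 12.6-fold (5045 ± 1970 against 419 ± 235, adjusted p = 0.00143). MIR210HG, the host transcript of the hypoxia-induced microRNA miR-210, rose 8.24-fold, TP53INP1 7.98-fold, the cannabinoid receptor gene CNR1 7.64-fold, FCMR, the IgM Fc receptor gene, 7.5-fold, SLC2A3 7.33-fold, DDIT4 6.86-fold, the deubiquitinase gene OTUD1 6.77-fold, YPEL3 6.54-fold and N4BP2L1 6.23-fold. The suspension signals of CNR1 (35.1) and N4BP2L1 (22.54) lay under the filter signal of 53.4 and were not shown to be above background, so the size of these folds is uncertain. For CNR1 and N4BP2L1 other probe sets gave smaller changes, and these became the brightest when a MALC array was left out: the log2 change of CNR1 was then 0.23 to 0.27, and that of N4BP2L1 0.26 without MALC 2 (adjusted p = 0.0986) and 0.29 without MALC 3 (0.0956). The 10 largest falls began with LMNB1, lamin B1, 4.58-fold lower (620.8 ± 619 against 2168 ± 466, adjusted p = 0.019), SDF2L1, and RCC1, the nucleotide exchange factor of RAN, 3.03-fold lower. LINC02909, GDAP1, PLAA, CCDC85B, PIGW, CHAC2 and RPP40 were 2.92-, 2.75-, 2.71-, 2.65-, 2.63-, 2.56- and 2.53-fold lower. Other probe sets gave smaller falls on the log2 scale for CCDC85B (−0.24 against −1.41), PLAA (−0.37 and −0.97 against −1.44) and RCC1 (−0.65 against −1.60). For GDAP1 they gave −0.41 and −1.53 beside −1.46. LMNB1 had 1333 in MALC 1 but 218 and 311.2 in MALC 2 and MALC 3, and RCC1 1080 against 368.2 and 446.5. The LMNB1 and PLAA calls were lost without MALC 2, MALC 3, suspension 2 or suspension 3 (adjusted p 0.0557 to 0.0694 and 0.0537 to 0.0666).

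No gene list passed when the correlation between its members was estimated from these 6 arrays (0 of 26; 1 at an unadjusted p under 0.05), whereas fry, which asks only whether members move to 1 side on balance, called 17, 11 up and 6 down. The list calls rest on the preset correlation of 0.01. Without suspension 2 and suspension 3, where the lone suspension sample is assumed to vary like the MALC samples, these named genes lost their call (adjusted p 0.0541 to 0.36): LMNB1, RCC1, LINC02909, PLAA, NDUFS1, KIF11, RPL11, ATF3, PDIA3, HSPA5, CD37, LMO2, XBP1, DERL3, NLRC5, NCR3LG1 and BCL2. Their log2 changes kept their sign there, at 1.12 for CD37, 1.5 for NLRC5, −0.74 for KIF11, −0.73 for NDUFS1 and −0.93 for HSPA5, and fell in size most for BCL2 (0.13) and LINC02909 (−0.97). In the same fit 7 apoptosis genes rose and 1 fell, and the rises of the B cell and MHC class II lists numbered 5 and 10. In that fit MYC (0.0443) and the germinal centre (0.00344), chemokine (0.0173), immune checkpoint (0.0306) and immediate early (8.26e-05) lists passed. Without both arrays numbered 1 the p53 (0.0864) and apoptosis (0.102) lists were lost, and MS4A1 (log2 change −0.12, adjusted p = 0.00174), BCL6 (4.26e-07), MKI67 (5.39e-06), CDKN1A (0.0308) and the unfolded protein response list (0.00488) passed. The arrays left in each group were nearly alike, so these p-values rest on a small spread and can be small without larger effects. In this fit 19 B cell genes rose and 6 fell, 8 MHC class II genes rose and 2 fell, and the falls numbered 21 for oxidative phosphorylation, 12 for the amino acid response, 10 for the immediate early and 37 for the G2/M list. With the sample number as a block smaller shifts in member counts were seen in further lists, such as 17 oxidative phosphorylation falls, 10 p53 rises, 16 apoptosis rises, 17 NF-kB rises and 11 interferon rises.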

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

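The tests of explanations for the poly-A controls, the stromal transcripts and the early response transcripts were chosen only after the result was seen, whereas the splits of the arrays were planned. Control probe sets and probe sets that name no gene, which the gene comparisons leave out, held differences between the groups. The 4 poly-A controls, spiked into RNA before labelling, were higher in every MALC array than in every suspension array: dap 1.61-fold, thr 1.36-fold, phe 1.24-fold and lys 1.33-fold (exact two-sided permutation p = 0.1 for each, the smallest that 3 against 3 allows). Among 6672 probe sets with no gene symbol or several, 2651 changed, 1728 higher and 923 lower in MALC, and of those at least 2-fold in size 294 were higher and 38 lower. This share was no larger than that of all probe sets tested, of which 13649 of 32768 changed.

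Array brightness or hybridisation is argued against for the poly-A controls, since the 4 hybridisation controls, added after labelling, differed by a mean log2 of −0.044 (SD 0.1 over controls) against 0.306 or more for each poly-A control. A lower share of messenger RNA in the total RNA of MALC would raise all 4 by about 1 factor, as would a larger amount of spike-in; their mean rise was 0.462 on the log2 scale (SD 0.159), and the 2 cannot be told apart because neither amount was measured here. If the share of messenger RNA did fall in MALC, values scaled to each other between arrays may hide a drop common to most transcripts. The GAPDH control ratio and the upper signal percentiles also separated the groups, whereas the ACTB ratio and the hybridisation controls overlapped. A technical difference between the groups was not tested and could enter the gene calls.

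Stromal transcripts were seen in suspension 2 and in part in suspension 3. Of 17 fibroblast markers fixed before the data were examined, 6 were at least 2-fold higher in suspension 2 than in suspension 1 (COL1A1, COL1A2, COL3A1, COL6A3, POSTN and TAGLN), against a 95th percentile of 1 for 10000 random sets of genes with like numbers of probe sets, which is consistent with RNA or cells of a fibroblast type in that sample. The markers of the other cell types were not raised in this way, nor was the fibroblast marker DCN (129.8 against 105); COL1A1 reached 1130 and COL1A2 395, and 11 of the 17 markers lay above the level filter, THY1 at 744.2 or more in all arrays. A difference shared by all suspension samples is argued against for the raised probe sets only. Over these, suspension 1 exceeded the MALC mean by a median log2 of 0.0572, against 2.37 for suspension 2. They were picked as higher in suspension 2 than in suspension 1. That choice sets the 2.37 in part and favours a low value for suspension 1. A smaller amount of the same RNA in suspension 3 is argued against as well, because the excess in suspension 3 as a share of that in suspension 2 ran from 0.00136 (POSTN) to 0.312 (COL1A1). Each share, here and below, was taken from the gene's probe set with the largest rise in suspension 2 over suspension 1. Where the transcripts came from stays open.

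Early response transcripts were higher in suspension 2 and suspension 3 than in suspension 1 and, for EGR1, DUSP6 and EGR3, than in MALC. Of 30 members of the fixed immediate early list on the array, 8 were at least 2-fold higher in suspension 2 than in suspension 1. A batch of same-numbered samples that raised these genes alike in both groups is argued against. MALC 2 and MALC 3 differed from MALC 1 by a median log2 of −0.314, with −0.605 to −0.0938 over the genes. The median was 2.01 for suspension 2 and suspension 3 over suspension 1. That value was set in part by the choice of genes, made on suspension 2 over suspension 1. Other variation shared by same-numbered samples is not excluded by this. The source of the stromal transcripts cannot be told apart as a cause: the excess in suspension 3 was a median 0.961 of that in suspension 2, above the highest stromal share of 0.312, but the stromal shares were not constant themselves. A difference in handling or growth state between the suspension samples was not tested.

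The 10 splits of 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 5877 genes changed, 2611 higher, 3266 lower and 493 at least 2-fold, and the highest of the other splits in limma 0 for each, so that 1 of 10 splits reached each of these counts. At an unadjusted p under 0.05 the other splits gave 45 to 408 genes and the real split 7087; every other split mixes the groups, so that the difference between them adds to its spread and in part remains in its contrast. For gene lists at the preset correlation the real split called 12 lists higher and 5 lower, and the highest of the other splits was 16, taking their larger direction. Counting the real split itself, 5 of the 10 splits had 12 or more and 9 had 5 or more. Of the 3 other splits that part all 3 pairs of sample numbers, none called a gene, and they called 13, 16 and 7 lists in 1 direction and 0, 5 and 2 in the other.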

How the results depend on the processing

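Chosen after seeing the data were the fits without suspension 2 and suspension 3, without both arrays numbered 1, without a pseudocount, and with the block and an estimated correlation. Of the fits of 26 lists under the alternatives, 536 kept direction and side of the threshold, 59 lost and 19 gained a call and 10 reversed; for named genes these numbers were 1858, 70, 12 and 7. The genes changed (5877) became 8880 with array weights, 2855 without suspension 2 and suspension 3 and 13649 over probe sets; the higher ones (2611) 1469 and 6948 under the last 2, and the lower ones (3266) 5230, 1386 and 6701. With arrays left out in turn the total ran from 3993 (without MALC 2) to 6491 (without MALC 1), higher from 1880 to 2859, lower from 2113 to 3632, at least 2-fold from 380 to 706, lists higher from 9 to 14 and lists lower from 4 to 6. Fewer arrays or more features tested may account for part of this. The total rose, however, to 6491 without MALC 1, to 7724 without both arrays numbered 1 and to 8880 with array weights, and the cause was not tested. The lists called, 12 higher and 5 lower, were 0 and 0 with an estimated correlation, and 0 and 0 with the replicate block and an estimated correlation (smallest adjusted p 0.423).

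With the replicate block 6396 genes changed (5702 shared), and the block added the unfolded protein response and immune checkpoint lists, BCL6, FN1 and EGR1 and ended the call of BST2; it changed no other call of the 26 fixed lists or of the genes named in the report, but shifted counts of list members. Among lists that passed in neither direction, the amino acid response median was −0.0881 with array weights, −0.147 without MALC 1, −0.0944 without both arrays numbered 1 and −0.0214 with fry, each with direction down, and up to 0.039 with an array left out. The immediate early median ran from −0.0338 to 0.214 with an array left out, turned in direction at −0.0297 without suspension 1 and −0.0782 without both arrays numbered 1, and was 0.645 (adjusted p = 8.26e-05; range over alternatives up to 0.881) without suspension 2 and suspension 3. The plasma cell direction turned up at medians of −0.0208 (quantile normalization), −0.0472 (mean of probe sets), −0.00699 (no _s_at or _x_at probe sets) and −0.00589 (without suspension 2 and suspension 3). For ATF3 (up to 1.43 with an array left out) the value was −0.0215 without MALC 1 and −0.0572 without both arrays numbered 1. There another probe set, then the brightest, stood for the gene, so this is no reversal of the probe set reported above. MS4A1 (down to −0.191 with an array left out) turned to 0.0137 without MALC 1, 0.0112 without suspension 2, 0.00722 without suspension 3 and 0.21 without suspension 2 and suspension 3; BCL2 turned to −0.0394 without _s_at and _x_at probe sets. Beyond the changes of probe set for ATF3 and BCL2, the cause was not tested. The share of changed genes that were higher was 44.4%, 40.9% after quantile normalization and 38.6% after median centring. No detection calls were at hand, so signal over background limits what can be said of genes near the filter signal of 53.4.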

Other observations

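The gene families in this part, the FOXO list and its test were chosen only after the gene values were seen. Of 75 mitochondrial ribosomal protein genes 59 fell and 1 rose in MALC, with a median log2 change of −0.44 and MRPL4 2.10-fold lower, and of 21 mitochondrial import genes 18 fell, with TOMM40 2.08-fold lower. Of 30 proteasome subunit genes 24 fell and none rose, of 30 RNA polymerase subunit genes 24 fell and 1 rose, of 8 CCT chaperonin genes 7 fell, of 20 Sm and LSm genes 14 fell and of 21 nucleoporin genes 14 fell and 1 rose. Each of these families stood below other genes with camera at the preset correlation (adjusted p 8.22e-11 to 0.00101 over 14 families), and none with an estimated correlation (adjusted p = 0.326 for each).

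Of 6 metallothionein genes 4 rose, MT2A 1.78-fold, and of 18 lysine demethylase genes 8 rose and 2 fell, among the risers KDM3A (2.87-fold) and KDM4B (2.06-fold). Of 18 genes of the histone clusters 6 rose and 2 fell, with H2BC5 5.97-fold and H2AC6 5.80-fold higher, and 10 did not pass. Of 480 divergent and antisense transcripts 125 rose and 43 fell, with PIK3IP1-DT 4.87-fold higher, beside its neighbour PIK3IP1, which rose 4.43-fold. Of 49 RAB genes 15 rose and 5 fell, and of 353 ZNF genes 96 rose and 79 fell. With camera at the preset correlation the adjusted p was 0.00612 for metallothioneins, 0.00109 for demethylases, 0.00441 for divergent and antisense transcripts and 0.0171 for RAB genes, all with direction up, although the medians of the latter pair were −0.000449 and 0.0347 on the log2 scale. The histone (0.0621) and ZNF (0.0608) families did not pass, but passed with the sample number as a block (0.0206 and 0.048); with an estimated correlation none of the 6 did (adjusted p = 0.446 for histones and 0.326 for the others).

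One hypothesis is that FOXO transcription factors may be more active in MALC, with lower PI3K signalling. Of 28 tested FOXO target genes 16 rose and 2 fell, among the risers PIK3IP1, SESN3 (4.42-fold) and CDKN1B (3.76-fold), with p = 6.08e-06 at the preset correlation and p = 0.0106 with an estimated correlation. The list was written after several members had been seen to rise, so that this test cannot tell whether the hypothesis holds; the adjusted p over the 14 families was 0.148 with an estimated correlation, and protein activity was not measured here.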
